A study of Citrus x paradisi x Citrus trifoliata and Citrus sinensis x Citrus trifoliata with 12 samples.

How the data were processed

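Root-tip RNA of Carrizo citrange and Swingle citrumelo, both grafted with a sweet orange scion and grown in volcanic or calcareous soil, was measured on 12 single-colour CombiMatrix arrays, 3 per group. Per the labels' protocols, each biological replicate was total RNA from a pool of 3 plants, amplified and labelled with Cy5. Groups and replicate numbers were taken from the labels alone. The names of the deposited files give Troyer as the rootstock of all 6 libraries that the labels call Carrizo, and the labels were followed, so which of the names holds was not settled. The labels call the replicates biological and give no further detail on plots or blocks.

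Per the file headers, the arrays were scanned at 635 nm and the spots were quantified with GenePix Pro 7.0.10, with no normalization. The deposited scanner files hold the intensity of each of 94928 spots, as the median and mean of its foreground pixels and the median of its local background, and the percent of its pixels that were saturated. The authors also deposited a table of intensity values per probe. Its scale, centring and direction are not given in the sources used here. Set against the scanner files, each of its columns had the rank order of the per-probe median of the foreground medians of its own array (Spearman correlation at least 0.99999, against at most 0.978 with another array). Column medians lay between 440.7 and 441.3, so the table is linear and was equalised between arrays, by a method that is not stated. It was used as an alternative, after log2.

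The array held 7697 target probes of 35 to 40 nucleotides, 1 per target identifier, each on 11 to 15 spots, with 47 negative control probes on 567 spots, 19 quality control probes and 87 other probes named by sequence accessions. Probe names end in S (4093 targets) or in X and a number (3604 targets), and the meaning of the suffix is not given in the sources used here. No table that pairs probes with genes was used here. The 28 gene lists fixed before the data were examined could therefore not be matched, 0 of 28, and no list was tested. By the rule fixed for that case, at most 2 probes higher and 2 lower are named per comparison: those with the largest fold among calls whose groups do not overlap and that were detected on all arrays of the higher group, or, where no probe passed, those with the smallest unadjusted p, without the last 2 conditions for the interaction and the average.

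Foreground medians were corrected with the local background by normexp with an offset of 50, quantile-normalized over all non-empty spots, transformed to log2 and averaged over the spots of a probe, in R 4.3.3 with limma 3.58.1. Quantile normalization gives every array one distribution, so a shift of most transcripts in one direction would not be seen. A probe was called detected on an array when the geometric mean of its raw foreground medians exceeded the 95th percentile of that array's negative control spots, and probes detected on at least 3 of 12 arrays were tested, 2828 in all. Of the tested probes 28.4% had the suffix S, against 53.2% of all targets. A means model of the 4 groups was fitted to all 12 arrays with lmFit and eBayes, which leaves 8 residual degrees of freedom, and p-values were adjusted by the method of Benjamini and Hochberg within each of 6 comparisons at a threshold of 0.05. All tests were two-sided. Differences are given as calcareous minus volcanic, or Swingle minus Carrizo.

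Where a probe was not detected on any array of the dimmer group, the fold is a lower bound against the lowest normalized value of a detected target on each array of that group, or the probe's own value where higher. Between 4 and 11 targets per array had saturated pixels in most of their spots. Median target foreground lay between 560 and 1061, median background between 48 and 165, and the median negative control between 368 and 905. Photomultiplier gain ranged from 460 to 540 and laser power from 33% to 40%.

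The headers' image records place the 12 arrays on 3 slides that were each hybridised 4 times, scanned over 5 days. Deviations of spots from their probe's mean, which follow the physical slide, correlated between 0.273 and 0.889 for the 18 pairs of arrays on one slide and between -0.0314 and 0.332 for the 48 pairs on different slides. The first slide carried, in order, Carrizo volcanic replicates 1 and 3, Carrizo calcareous replicate 2 and Swingle calcareous replicate 1. The second carried Carrizo calcareous replicate 1, Carrizo volcanic replicate 2, Swingle calcareous replicate 3 and the library labelled Swingle volcanic replicate 3. The third carried Carrizo calcareous replicate 3, Swingle calcareous replicate 2, the library labelled Swingle volcanic replicate 2 and Swingle volcanic replicate 1. Slide, scan day and order of use were tried as blocks. Within scan days, the soils meet in Swingle only as Swingle calcareous replicate 1 against the libraries labelled Swingle volcanic replicates 2 and 3. In Carrizo they meet only as calcareous replicates 1 and 3 against volcanic replicate 1. With the scan day as a block the soil differences, their interaction and their average rest on these libraries alone. Pearson correlations across the tested probes lay between 0.843 and 0.977 within groups and between 0.774 and 0.956 between groups, so the ranges overlap.

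Same replicate numbers were checked for pairing by correlating the deviations of libraries from their group means. Between the 2 Swingle groups the correlations for numbers 1, 2 and 3 were 0.225, 0.152 and 0.167, which counts as pairing under the limit of 0.1 set in advance, although no label ties the numbers to a shared plot or day. Deviations from a group mean sum to 0, so the 3 correlations are not independent. In both groups replicates 2 and 3 were each other's nearest library, so replicate 1 standing apart in both could give all 3. In the other comparisons at least 1 correlation was below 0.

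The fitting step was tested on simulated data with 2828 probes of which 200 were changed. It recovered between 59% and 68.5% of changes of 1 log2 unit and between 95.5% and 96.5% of changes of 2 log2 units, in each of the 4 comparisons of 2 groups. Of the calls in these simulations, between 3.5% and 6.25% were false. The simulated values were independent normal draws with the residual SD of each probe. They held no effect of slide, scan day or order of use and no correlation between probes, so these shares are not the power in the real data. Alternatives fixed before the data were examined were no background correction, an offset of 16, cyclic loess, scaling to the median or the 75th percentile, no filter or detection on at least 6 arrays, the deposited table, blocks for replicate number, slide and scan day, fits of only the compared groups, array weights, trended and robust moderation, an added 2-fold limit and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Other tests across many probes than those named were not run.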

Results

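The series measured root-tip RNA of 2 citrus rootstocks on 2 soils. Carrizo citrange, a hybrid of sweet orange and trifoliate orange, is described in the series as tolerant of iron deficiency. Swingle citrumelo, a hybrid of grapefruit and trifoliate orange, is described as sensitive to it. Plants of both rootstocks carried a sweet orange scion and grew either in a volcanic soil with 0% active lime, the control, or in a calcareous soil with 10% active lime. Active lime is finely divided calcium carbonate, which keeps soil alkaline and iron poorly soluble. It was not varied within a soil, so its effect cannot be told apart from other differences between the soils. Each of the 4 groups had 3 biological replicates, each a pool of root tips from 3 plants, and each RNA was hybridised to 1 single-colour array, 12 arrays in all. Between 24.9% and 40.8% of the 7697 target probes were above the negative controls on an array, and 2828 probes that passed this limit on at least 3 arrays were tested. The files pair each probe with its sequence and not with a gene name, so probes are reported by identifier and sequence and the organism's genes behind them are not named. The number of arrays limits the precision of every value.

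Most of the calls came from the rootstocks on calcareous soil, the comparison of the sensitive with the tolerant rootstock on the soil with 10% active lime. On this soil 32 probes differed, 19 higher and 13 lower in Swingle than in Carrizo (limma, adjusted p under 0.05). Of these, 15 were more than 2-fold higher and 7 more than 2-fold lower, with folds against a group without detection taken as lower bounds. Of the higher probes 10 were detected on no Carrizo calcareous array and on all 3 Swingle calcareous arrays. Of the lower probes 7 were detected on no Swingle calcareous array, 6 of them on all 3 Carrizo calcareous arrays. The remaining calls, detected in both groups, had log2 differences, Swingle minus Carrizo, between 0.995 and 2.95 for the 9 higher and between -0.86 and -2.08 for the 6 lower probes.

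The probe id_3857_513_37_X6 (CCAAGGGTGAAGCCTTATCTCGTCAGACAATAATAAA) had a mean log2 intensity of 12.92 ± 0.41 (SD, n = 3) in Swingle on calcareous soil. In Carrizo on the same soil it measured 7.46 ± 0.29 (SD, n = 3), which was not well above background. The mean signal was at least 9.49-fold higher in Swingle (limma adjusted p = 0.0152), and all 3 Swingle libraries were above all 3 Carrizo libraries. An allele difference under a probe was not tested, so here and below signals are compared between the rootstocks, not amounts of transcript. A second probe, id_2143_525_37_X6 (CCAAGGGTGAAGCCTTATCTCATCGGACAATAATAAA), stood at 13.08 ± 0.47 in Swingle and 8.10 ± 0.13 in Carrizo (SD, n = 3 each), at least 10.6-fold higher in Swingle (limma adjusted p = 0.0152). Its sequence differs from that of the first at 2 of 37 positions, G22A and A25G, counted from 1 at the 5′ end of the printed sequence, so the probes can share target RNA and are not independent. In the other direction, id_2643_224_40_X2 (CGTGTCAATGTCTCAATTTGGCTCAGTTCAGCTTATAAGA) averaged 8.61 ± 0.37 in Swingle, not well above background, and 12.80 ± 0.98 in Carrizo (SD, n = 3 each). It was at least 11-fold lower in Swingle (limma adjusted p = 0.0287). The probe id_1117_472_35_X2 (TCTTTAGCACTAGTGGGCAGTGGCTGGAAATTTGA) was at 7.96 ± 0.26 in Swingle and 11.29 ± 0.68 in Carrizo (SD, n = 3 each), at least 3.87-fold lower in Swingle (limma adjusted p = 0.0222). Each bound sets the mean of the brighter group against the lowest normalized signal of a detected probe on the arrays of the dimmer group.

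**Figure D1:**
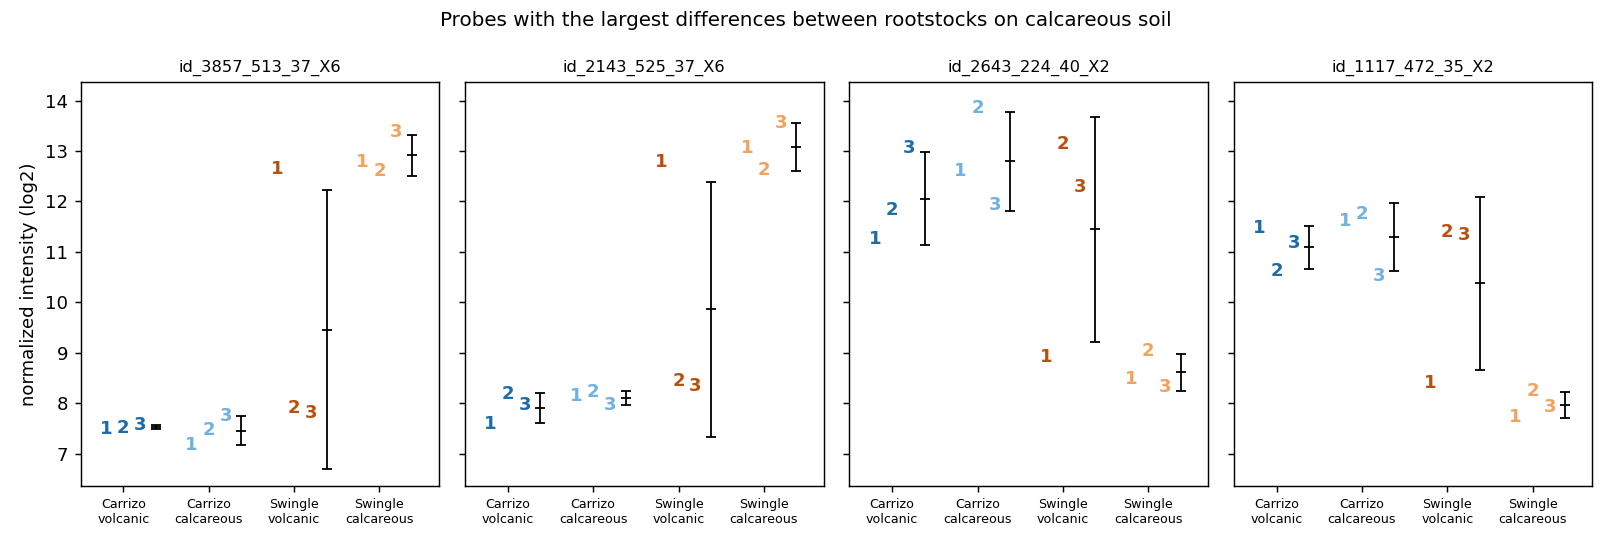
Normalized log2 intensity (vertical axis, same scale in every panel) of the 4 named rootstock probes in each of the 12 libraries, drawn as their replicate numbers, with the group mean and SD as bars. The 3 Swingle calcareous libraries stand apart from the 6 Carrizo libraries in each panel, and Swingle volcanic replicate 1 lies with the former while replicates 2 and 3 lie with the latter.

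All 32 called probes had 3 Swingle calcareous libraries on one side of the 3 Carrizo calcareous libraries. Over the 2828 tested probes, 19.1% had groups that did not overlap, where chance gives 10%. Each of the 3 slides carried 1 Carrizo and 1 Swingle calcareous library, but on every slide the Carrizo libraries were hybridised before the Swingle libraries, so within a slide the rootstock is tied to the order of use. The rootstocks shared 1 of the 5 scan days. For id_3857_513_37_X6 the within-slide differences, to values not above background in the dimmer group, were 5.30, 6.21 and 4.86 log2 units, and for id_2643_224_40_X2 they were -5.37, -4.30 and -2.89. With the slide as a block limma called 18 probes, and with the order of use of the slide as a block, an alternative added after seeing the data, it called 0. With that last block the differences of the 4 named probes, to the same background values, were 5.08, 4.41, -4.65 and -3.01 log2 units in the order of their naming, with adjusted p between 0.127 and 0.286. The count rested on single libraries: it was 1 without Carrizo calcareous replicate 1, 15 without Carrizo calcareous replicate 2, 2 without Carrizo calcareous replicate 3, 61 without Swingle calcareous replicate 1, 1 without Swingle calcareous replicate 2, 1 without Swingle calcareous replicate 3 and 102 without Swingle volcanic replicate 1. The last library is in neither group compared and acts only through the spread that all groups share. For id_3857_513_37_X6 the SD was 2.76 in Swingle volcanic, against 0.41 in Swingle calcareous and 0.29 in Carrizo calcareous. A fit of only the 2 groups compared called 90 probes.

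The Swingle volcanic libraries did not share these differences equally. Of the 32 probes called on calcareous soil, Swingle volcanic replicate 1 lay nearer the Swingle calcareous than the Carrizo calcareous mean for 20, and the libraries labelled replicates 2 and 3 did so for 7 and 5. For id_3857_513_37_X6 replicate 1 measured 12.65 log2 units, close to the Swingle calcareous mean of 12.92, and the libraries labelled replicates 2 and 3 measured 7.91 and 7.81, close to the Carrizo volcanic mean of 7.52 ± 0.04 (SD, n = 3). For id_2643_224_40_X2 replicate 1 measured 8.92, and the libraries labelled replicates 2 and 3 measured 13.14 and 12.28. To place these libraries without using their own values, probes were taken that separated the 6 Carrizo libraries from the 3 Swingle calcareous libraries by a gap of at least 1 log2 unit. There were 28 such probes, 21 higher and 7 lower in Swingle. On a scale from 0 at the Carrizo mean to 1 at the Swingle calcareous mean, the median position of Swingle volcanic replicate 1 was 0.924, that of the library labelled replicate 2 was -0.00114 and that of the library labelled replicate 3 was 0.0484. Each Carrizo library, held out in the same way, had a median position between -0.0482 and 0.0617. Every mean of the Swingle volcanic group below therefore averages libraries at 2 distinct levels for such probes. Those levels also widen the spread that all groups share, and so the SE in every comparison, for such probes.

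**Figure D2:**
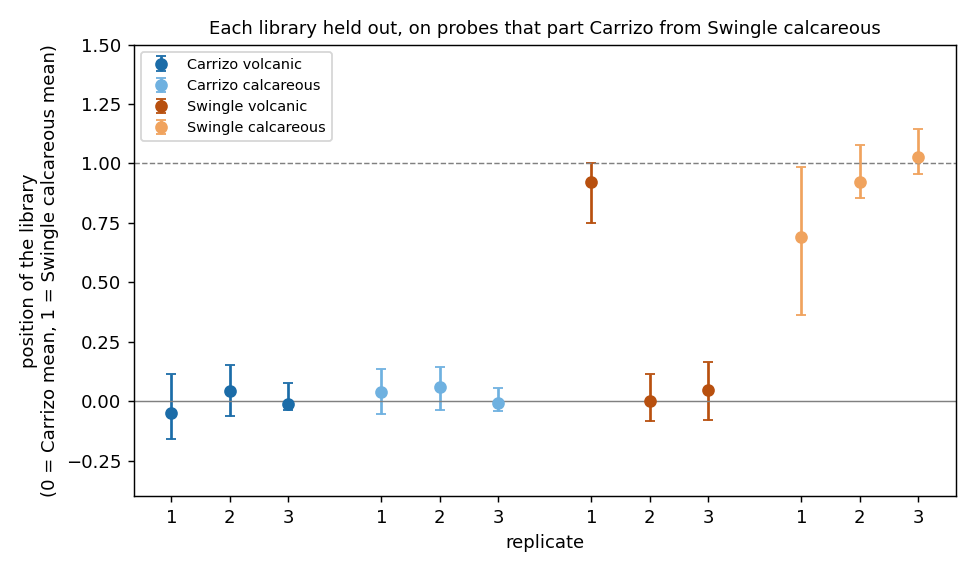
Median position of each library (points, with bars from the lower to the upper quartile over probes) on the scale from 0 at the Carrizo mean to 1 at the Swingle calcareous mean, with the plotted library held out of the choice of probes. The 6 Carrizo libraries and the libraries labelled Swingle volcanic replicates 2 and 3 lie between -0.0482 and 0.0617, Swingle volcanic replicate 1 lies at 0.924, and Swingle calcareous replicates 1, 2 and 3 lie at 0.692, 0.924 and 1.03.

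On volcanic soil, the control soil, 2 probes were higher in Swingle than in Carrizo and 0 were lower (limma, adjusted p under 0.05). On this soil the rootstocks shared neither a scan day nor a place in the order of slide use. Carrizo came earlier in both, so the rootstock difference cannot be told apart from scan day or order of use. The probe id_1958_31_36_X6 (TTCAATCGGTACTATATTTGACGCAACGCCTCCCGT) averaged 14.80 ± 0.40 in Swingle and 13.05 ± 0.24 in Carrizo (SD, n = 3 each), a difference of 1.76 ± 0.28 log2 units (SE, limma adjusted p = 0.0443). The probe id_4207_273_38_X4 (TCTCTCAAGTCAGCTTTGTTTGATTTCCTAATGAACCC) averaged 13.00 ± 0.21 in Swingle and 11.65 ± 0.29 in Carrizo (SD, n = 3 each), a difference of 1.36 ± 0.22 log2 units (SE, limma adjusted p = 0.0443). For both probes all 3 Swingle libraries, including those labelled replicates 2 and 3, were above all 3 Carrizo libraries. The second of them was also higher in Swingle on calcareous soil, by 0.995 ± 0.222 log2 units (SE, limma adjusted p = 0.049), and it was the 1 probe called on both soils, where independent lists would share 0.0226. The lists are not independent, since both come from the same fit with a shared spread per probe.

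At an unadjusted p under 0.05 there were 222 probes on volcanic soil against 141 expected by chance, and 8.56% of the tested probes had groups that did not overlap. This count rested on single libraries, with 111 probes without Carrizo volcanic replicate 1 and 445 without Carrizo volcanic replicate 2. Rootstock differences on the 2 soils, which share no arrays, had a Pearson correlation of 0.413 and a Spearman correlation of 0.324 across probes, which are not independent replicates. On both soils the Carrizo libraries came before the Swingle libraries on a slide, so an effect of that order would enter both differences. The correlation was not recomputed with a block or without single libraries. Of the 32 probes called on calcareous soil, 30 had the same direction in the means on volcanic soil, against 60.8% of all tested probes, but the libraries labelled Swingle volcanic replicates 2 and 3 both had that direction against the Carrizo volcanic mean for only 20, and both had the other for 5. Without the libraries labelled Swingle volcanic replicates 2 and 3, an alternative added after seeing the data that assumes the lone remaining library to vary like the other groups, 60 probes were called on volcanic soil, 53 higher and 7 lower in Swingle, and 89 on calcareous soil. Slide 2 held the only within-slide comparison, 1 library of each rootstock, which gave 1.94 log2 units for id_1958_31_36_X6 and 1.07 for id_4207_273_38_X4. No probe was called with the slide as a block or when any 1 Carrizo library, Swingle calcareous replicate 3 or the library labelled Swingle volcanic replicate 2 or 3 was left out (0 in each fit), and 4 were called without Swingle volcanic replicate 1. Each of the 2 named probes fell short of the threshold under 23 alternatives and kept to it under 10. Their differences stayed between 1.39 and 2.14 log2 units for id_1958_31_36_X6 and between 1.06 and 1.59 for id_4207_273_38_X4.

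In Swingle, the sensitive rootstock, no probe passed the threshold between calcareous and volcanic soil. Limma called 0 of 2828 probes, with a smallest adjusted p of 0.0986. At an unadjusted p under 0.05 there were 381 probes, 231 higher and 150 lower on calcareous soil, against 141 expected by chance, and 18.6% of the probes had groups that did not overlap. The count of 381 was 144 without Swingle calcareous replicate 3, 641 without Swingle volcanic replicate 1 and 186 without the libraries labelled Swingle volcanic replicates 2 and 3. By the same lower bounds, a difference of more than 2-fold was measured for 64 probes, 54 higher and 10 lower. Before any bound, the widest differences were 3.46 log2 units for id_3857_513_37_X6 and -2.84 for id_2643_224_40_X2. On both, the libraries labelled replicates 2 and 3 lay near the Carrizo level and replicate 1 near the Swingle calcareous level. How many of the 64 probes rest on those libraries was not counted.

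Of the probes with the smallest p, id_1189_467_39_X4 (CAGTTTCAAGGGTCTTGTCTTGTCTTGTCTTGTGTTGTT) measured 15.47 ± 0.45 on calcareous and 13.67 ± 0.30 on volcanic soil (SD, n = 3 each), a difference of 1.80 ± 0.31 log2 units (SE, limma adjusted p = 0.0986). The probe id_4172_24_35_X6 (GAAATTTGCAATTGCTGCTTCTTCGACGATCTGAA) measured 10.89 ± 0.09 and 9.38 ± 0.66 (SD, n = 3 each), a difference of 1.52 ± 0.28 log2 units (SE, limma adjusted p = 0.0986). It was detected on 1 of the 3 volcanic arrays, and its volcanic values were 10.12 in replicate 1 and 9.16 and 8.85 in the libraries labelled replicates 2 and 3. With lower values on calcareous soil, id_6450_367_37_X3 (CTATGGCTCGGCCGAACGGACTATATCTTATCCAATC) measured 10.88 ± 0.13 against 11.81 ± 0.09 (SD, n = 3 each), a difference of -0.93 ± 0.18 log2 units (SE, limma adjusted p = 0.0986). The probe id_4389_163_35_X3 (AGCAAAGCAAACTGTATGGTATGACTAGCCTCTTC) measured 10.32 ± 0.09 against 11.81 ± 0.90 (SD, n = 3 each), a difference of -1.49 ± 0.36 log2 units (SE, limma adjusted p = 0.257). Within the 2 slides that held both Swingle groups id_1189_467_39_X4 differed by 2.30 and 1.90 log2 units and id_4389_163_35_X3 by -1.99 and -1.20. Against replicate 1 as the only volcanic library, without the libraries labelled replicates 2 and 3, the differences were 1.45 log2 units for id_1189_467_39_X4, 0.77 for id_4172_24_35_X6, -0.82 for id_6450_367_37_X3 and -0.45 for id_4389_163_35_X3.

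**Figure D3:**
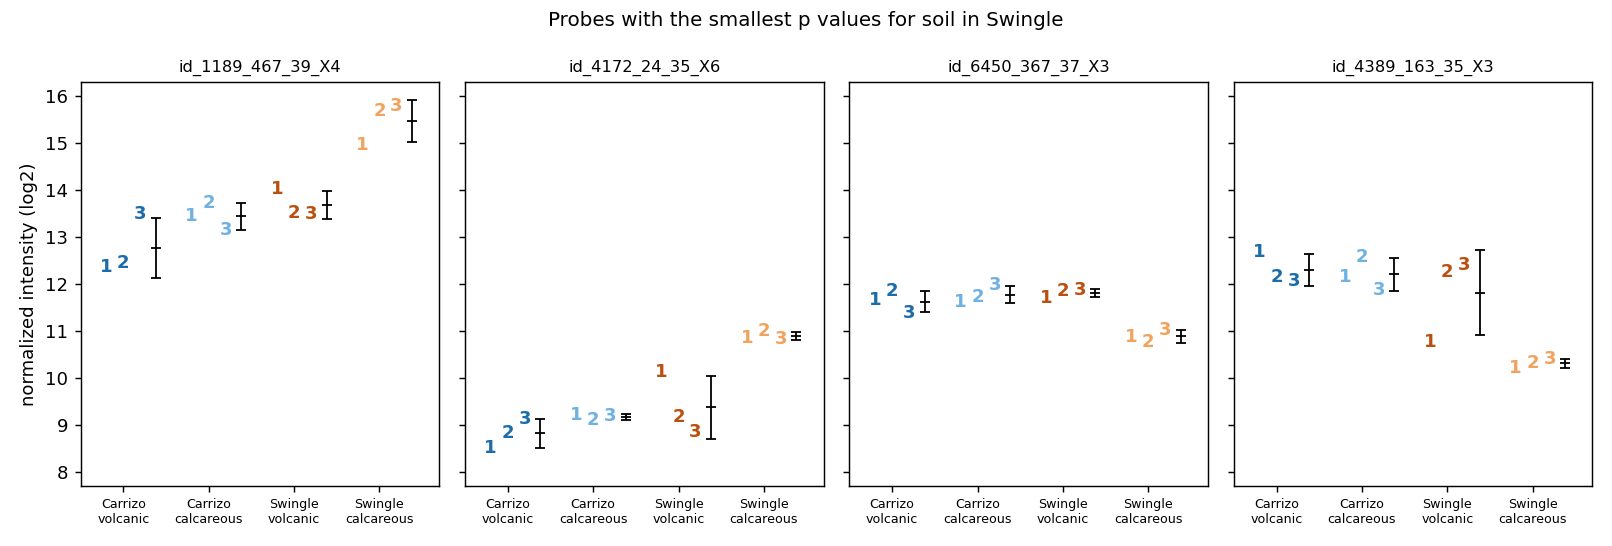
Normalized log2 intensity (vertical axis, same scale in every panel) of the 4 named probes of the Swingle soil comparison in each of the 12 libraries, drawn as their replicate numbers, with the group mean and SD as bars. In each panel the 3 Swingle calcareous libraries do not overlap the 3 Swingle volcanic libraries, which was a condition for choosing these probes and so is no evidence of a soil difference. In the main fit of all 12 libraries no probe reached an adjusted p under 0.05, the smallest being 0.0986.

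Deviations of Swingle libraries with the same replicate number correlated positively, which does not establish pairing since these values are not independent. With the replicate number as a block in a fit of the 6 Swingle libraries alone, an alternative added after seeing the data, limma called 26 probes, 23 higher and 3 lower on calcareous soil. The same block in the fit of all 12 libraries gave 0, as did the slide as a block, whereas the scan day as a block gave 36. With the scan day as a block the Swingle difference is that of Swingle calcareous replicate 1 against the libraries labelled Swingle volcanic replicates 2 and 3. It is therefore no soil difference freed of batch. Without Swingle volcanic replicate 1 there were 85 calls, 67 higher and 18 lower, without Swingle calcareous replicate 1 there were 10, without Carrizo volcanic replicate 3 there was 1, and without the libraries labelled Swingle volcanic replicates 2 and 3 there were 0.

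In Carrizo, the tolerant rootstock, no probe passed the threshold between the soils. Limma called 0 of 2828 probes, with a smallest adjusted p of 0.345, and 115 probes had an unadjusted p under 0.05 against 141 expected, a count that was 43 without Carrizo calcareous replicate 2 and 268 without Carrizo volcanic replicate 3. A difference of more than 2-fold, by the same lower bounds, was measured for 14 probes, 12 higher and 2 lower on calcareous soil, and 8.45% of the probes had groups that did not overlap, where chance gives 10%. The probe id_4794_164_37_X11 (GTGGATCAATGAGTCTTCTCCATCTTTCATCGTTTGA) measured 12.50 ± 0.59 on calcareous and 10.95 ± 0.40 on volcanic soil (SD, n = 3 each), a difference of 1.54 ± 0.32 log2 units (SE, limma adjusted p = 0.345). The probe id_202_929_37_X2 (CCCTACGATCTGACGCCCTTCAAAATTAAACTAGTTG) measured 11.60 ± 0.38 and 10.46 ± 0.14 (SD, n = 3 each), a difference of 1.14 ± 0.24 log2 units (SE, limma adjusted p = 0.345). Differences in the other direction were -0.63 ± 0.21 log2 units for id_2853_522_38_X4 (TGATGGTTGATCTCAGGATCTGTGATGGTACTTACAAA) and -1.12 ± 0.38 for id_5988_1070_35_S (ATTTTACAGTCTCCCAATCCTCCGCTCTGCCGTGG) (SE, limma adjusted p = 0.952 for both). Within the 2 slides that held both Carrizo groups id_4794_164_37_X11 differed by 2.13 and 1.44 log2 units. Limma called 1 probe without the library labelled Swingle volcanic replicate 3, 2 without Carrizo volcanic replicate 3, 1 without both libraries labelled Swingle volcanic replicates 2 and 3, and 0 with the slide as a block.

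Whether the soil difference was unlike in the 2 rootstocks was tested as the soil difference in Swingle minus that in Carrizo. Limma called 0 probes, with a smallest adjusted p of 0.319, and 155 probes had an unadjusted p under 0.05 against 141 expected by chance, 87 without the library labelled Swingle volcanic replicate 3 and 313 without Carrizo volcanic replicate 2. The smallest p belonged to id_202_929_37_X2, which was 1.14 log2 units higher on calcareous soil in Carrizo and differed by -0.65 in Swingle, so that the interaction was -1.78 ± 0.33 log2 units (SE, limma adjusted p = 0.319). For id_3363_371_38_X2 (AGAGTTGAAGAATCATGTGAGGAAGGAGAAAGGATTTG) the interaction was -1.19 ± 0.26 log2 units (SE, limma adjusted p = 0.581), but it was detected on no Swingle array. Among positive interactions the smallest unadjusted p belonged to id_6400_84_36_X3 (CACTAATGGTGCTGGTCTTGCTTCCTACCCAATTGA) with 0.89 ± 0.27 and id_3722_1022_38_X2 (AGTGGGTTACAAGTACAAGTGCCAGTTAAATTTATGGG) with 1.14 ± 0.35 log2 units (SE, limma adjusted p = 0.804 for both). The latter probe was not well above background in 3 of the 4 groups. The count was 38 without Swingle volcanic replicate 1, 1 without Swingle calcareous replicate 1, 0 without the libraries labelled Swingle volcanic replicates 2 and 3, 0 with the slide and 10 with the scan day as a block.

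Averaged over the rootstocks, the soil difference gave 0 calls by limma, with a smallest adjusted p of 0.231, and 375 probes at an unadjusted p under 0.05, 183 higher and 192 lower on calcareous soil, against 141 expected by chance. Leaving out 1 library gave between 154 such probes, without Swingle calcareous replicate 3, and 634, without Carrizo volcanic replicate 3. The largest of the named differences was that of id_1189_467_39_X4, 1.24 ± 0.22 log2 units (SE, limma adjusted p = 0.231). The probe id_3598_1736_36_X3 (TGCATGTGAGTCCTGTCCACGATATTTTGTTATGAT) had similar differences in both rootstocks and did not pass the threshold. It measured 14.93 ± 0.09 against 14.27 ± 0.28 in Carrizo and 15.10 ± 0.18 against 14.45 ± 0.11 in Swingle (SD, n = 3 each), on average 0.65 ± 0.13 log2 units (SE, limma adjusted p = 0.288). Lower averages on calcareous soil were measured for id_3820_1059_36_S (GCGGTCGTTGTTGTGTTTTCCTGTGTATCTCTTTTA), -0.63 ± 0.17, and id_1118_656_36_S (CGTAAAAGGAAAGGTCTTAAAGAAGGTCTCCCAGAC), -0.67 ± 0.20 log2 units (SE, limma adjusted p = 0.369 for both). The count was 45 without Swingle volcanic replicate 1, 4 without Swingle calcareous replicate 1, 1 without Carrizo volcanic replicate 3, 0 without the libraries labelled Swingle volcanic replicates 2 and 3, 0 with the slide and 16 with the scan day as a block.

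The soil differences of the 2 rootstocks, which share no arrays, were compared across probes. They had a Pearson correlation of 0.258 and a Spearman correlation of 0.369 across 2828 probes, which are not independent replicates, and 67.0% of the probes had the same sign in both. No probe was called in both rootstocks. At an unadjusted p under 0.05 there were 3 probes higher on calcareous soil in both rootstocks, against 5.64 expected for independent lists, 3 lower in both against 2.44 expected, and 7 with opposite directions. These lists too share the spread per probe of the same fit. The correlation rested on single libraries and on the batch: it was -0.119 without Carrizo volcanic replicate 2, 0.389 without Carrizo volcanic replicate 3, 0.139 with the slide as a block and -0.0874 with the scan day as a block. With the scan day as a block each soil difference rests on 3 libraries of a single scan day.

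**Figure D4:**
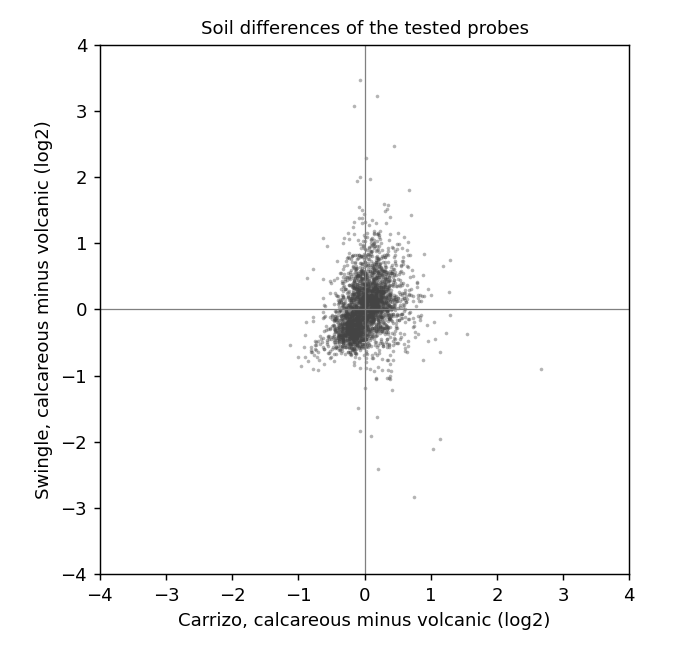
Difference between calcareous and volcanic soil (log2 units) in Carrizo (horizontal axis) and Swingle (vertical axis), 1 point per tested probe, 2828 in all. The spread is larger along the Swingle axis, where 64 probes differed by more than 2-fold against 14 in Carrizo, with groups without detection set to the lowest detected signal, and the Pearson correlation is 0.258. The widest Swingle differences in either direction belong to id_3857_513_37_X6 and id_2643_224_40_X2, on which the libraries labelled Swingle volcanic replicates 2 and 3 lay near the Carrizo level.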

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

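The tests of explanations in this part were all chosen after the results were seen.

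Signal appeared in probes outside the comparisons. Of 87 probes named by sequence accessions and not part of the target set, 20 were above the 95th percentile of the negative controls on all 12 arrays. Leaving aside 4 of these from a separate naming series, the other 16 moved together over the 12 arrays, with a lowest correlation between any 2 of them of 0.833. Their median log2 level was highest in Swingle volcanic replicate 1, at 14.12, and lowest in Swingle calcareous replicate 2, at 11.28, a difference of 2.85 after normalization. The next highest library stood at 12.87. No label says what these probes measure, and no explanation was tested.

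The libraries labelled Swingle volcanic replicates 2 and 3 lay at the Carrizo level on the 28 probes that separate Carrizo from Swingle calcareous, with median positions of -0.00114 and 0.0484, against 0.924 for Swingle volcanic replicate 1. A slide effect is argued against, since 3 of the 3 other Swingle libraries that share a slide with one of them lay nearer the Swingle calcareous level when held out. An exchange with Carrizo libraries of the series cannot be decided here. Although 0 of 6 Carrizo libraries lay nearer the Swingle level, each was held out alone. With 2 exchanged, the other would stay in the reference and remove the probes that separate the rootstocks. Scan day cannot be told apart, since the 2 libraries were scanned on one day with a single other library, Swingle calcareous replicate 1, whose held-out position was 0.692. A soil effect in Swingle, with replicate 1 as the library out of place, cannot be told apart from 2 libraries with a wrong rootstock, because the 0.924 of a single library decides between them. Single wrong labels, with either the 2 libraries or replicate 1 in the wrong group, and off-type plants in the pools stay open as hypotheses, and an allele difference under a probe was not tested.

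Swingle calcareous replicate 1 stood apart from replicates 2 and 3. Of 59 probes that separate replicates 2 and 3 from the 6 Carrizo libraries by at least 1 log2 unit, replicate 1 lay nearer Carrizo on 23, whereas replicates 2 and 3, held out in turn, did so on 0 of 33 and 0 of 30. On 21 of those 23 probes Swingle volcanic replicate 1 lay nearer Carrizo too, and on 31 of the other 36 it lay nearer Swingle calcareous, but a part of the soil effect missing from calcareous replicate 1 cannot be told apart from an effect shared by same-numbered Swingle libraries, whose deviations correlated at 0.225 for number 1. Scan day cannot be told apart, since replicates 2 and 3 were scanned on one day with a single Carrizo library, Carrizo calcareous replicate 2. With that library held out of the choice, 74 probes separated replicates 2 and 3 from the other Carrizo libraries, and replicate 1 lay nearer Carrizo on 32. On those 32 the median position of Carrizo calcareous replicate 2 was 0.208, against -0.118 to 0.187 for the other Carrizo libraries. Whether the plants, the label or the scan set replicate 1 apart stays open.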

How the results depend on the processing

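Mean of pixels, median of spots, order of slide use, slide as a random block, the replicate block in the Swingle libraries alone and leaving out libraries in doubt were chosen after seeing the data, and the other alternatives before. The cause was not tested except where fewer libraries or probes entered a fit. The planned choice between several probes of a target was not run, since each target has 1 probe, and the gene list alternatives were not run because no list could be matched. For single named probes, 610 of the values under the alternatives kept their direction and side of the threshold, 73 fell short of it, 34 newly passed it and none turned direction. Many of these directions could not turn. Alternatives such as the 2-fold limit, other moderation or leaving out a library outside the compared groups keep the difference itself. For comparisons of 2 groups the probes were chosen for groups that do not overlap, so leaving out a library cannot turn them.

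The 32 calls on calcareous soil became 16 with detection on at least 6 arrays, 18 with the slide block, 0 with order of slide use as a block, 90 in a fit of only the 2 groups, 581 with array weights, 89 without both libraries in doubt (the libraries labelled Swingle volcanic replicates 2 and 3) and 144 without these and Swingle calcareous replicate 1. Leaving out each library in turn gave 1 to 102. The replicate block gave 29.

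The 2 calls on volcanic soil became 0 with cyclic loess, the 75th percentile, no filter, the deposited table, the replicate block, the slide block, the scan day block, only the 2 groups, trended and robust moderation, the mean of pixels, the median of spots and order of slide use. They became 1 with median scaling, 697 with array weights, 60 without both libraries in doubt and 38 without the 3 libraries in doubt. Leaving out each library gave 0 to 4.

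For soil in Swingle, the 0 calls became 3 with median scaling, 36 with the scan day block, 1231 with array weights, 1 without the 3 libraries in doubt and 26 with the replicate block in the Swingle libraries alone, and leaving out each library gave 0 to 85. For soil in Carrizo they became 1 in the fit of only the 2 groups, 3 with array weights, and 1 without both or all 3 libraries in doubt, with 0 to 2 when each library was left out. The interaction gave 10 with the scan day block and 439 with array weights, and 0 to 38 when each library was left out. The average soil difference gave 16 with the scan day block, 779 with array weights and 3 without the 3 libraries in doubt, and 0 to 45 when each library was left out. The replicate block gave 0 as well for soil in Carrizo, the interaction and the average, and for soil in Swingle when all 12 libraries were fitted. The counts with the scan day block rest, for Swingle, on Swingle calcareous replicate 1 against the libraries labelled Swingle volcanic replicates 2 and 3 alone.

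The correlation of the 2 soil differences, 0.258, was -0.0874 with the scan day block, 0.0845 with array weights and 0.0567 with order of slide use, and -0.119 to 0.389 when each library was left out, negative only without Carrizo volcanic replicate 2. The array weights ran from 0.26 for Carrizo volcanic replicate 2 to 3.94 for Swingle calcareous replicate 2. Under median scaling the median of all probes in the average soil difference was 0.10 log2 units, against 0.02 under quantile normalization. Signal over background limits the results: at most 40.8% of targets were detected on an array.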

Other observations

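The tests in this part were all chosen after the results were seen.

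The number of probes that separate the rootstocks depends on the gap asked for, 28 at 1 log2 unit and 172 at 0.25. The 28 probes that part the 6 Carrizo libraries from the 3 Swingle calcareous libraries by at least 1 log2 unit compare with at most 1 such probe for any other choice of 3 of these 9 libraries, over 84 choices. On the linear scale, the 21 of them that are higher in Swingle stood in Swingle volcanic replicate 1 at a median of 85.4% of the way from the Carrizo to the Swingle calcareous level. In the libraries labelled Swingle volcanic replicates 2 and 3 the medians were -0.123% and 0.85%, and the highest single probe reached 9.74% and 22.4%. A pool of 3 plants with 1 plant at the Swingle level would stand near 33.3%. Between successive uses of a slide the level rose from Carrizo to Swingle 4 times and fell back 2 times, both times at a library labelled Swingle volcanic replicate 2 or 3. With the gap lowered to 0.25 log2 units, 11.6% and 15.1% of 172 probes placed these 2 libraries nearer Swingle calcareous, against 4.89% to 17.8% for Carrizo libraries held out in the same way. Of the 32 probes called on calcareous soil, both libraries lay on the Swingle side for 3, and replicate 1 alone did so for 16.

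Over all tested probes, centred on their means, the library most correlated with Swingle calcareous replicate 1 was Swingle volcanic replicate 1 (r = 0.53 across probes), and Swingle calcareous replicates 2 and 3 were most correlated with each other (r = 0.826). The libraries labelled Swingle volcanic replicates 2 and 3 were most correlated with each other (r = 0.382), while no Carrizo library had its nearest neighbour in its own group. The nearest neighbour of Carrizo volcanic replicate 2 was the library labelled Swingle volcanic replicate 3 (r = 0.333). Each other Carrizo library was nearest to a Carrizo library of the other soil.

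Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. On calcareous soil the 32 calls were reached by the real split alone (1 of 10), with 0 as the highest of the others, and the 347 probes at an unadjusted p under 0.05 were also highest in the real split (1 of 10), with 238 next. On volcanic soil 2 of 10 splits gave as many calls as the real 2, with 4 in the highest other, and 4 of 10 gave as many probes as the real 222 at an unadjusted p, with 747 in the highest other. The split with 747 gave 0 calls, and what it follows was not tested. In Swingle the real split gave 0 calls, which 10 of 10 splits reach by necessity, with 1 in the highest other, and 2 of 10 gave at least 381 probes at an unadjusted p. The other of these, with 442, put Swingle calcareous replicate 1 and the libraries labelled Swingle volcanic replicates 2 and 3, all scanned on one day, against the remaining 3. With the scan day as a block, under which only the Swingle libraries of that day enter the Swingle difference, 36 probes were called. Like the real split, the split with 442 is one of 4 that part all same-numbered pairs. In Carrizo the real 0 calls are likewise reached by 10 of 10 splits, with 1 in the highest other, a split that follows a scan day, and 5 of 10 gave at least 115 probes at an unadjusted p, with 397 in the highest other and 123 in the split that follows the first slide. With the slide or the scan day as a block 0 probes were called there.

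For the interaction and the average soil difference the real 0 calls are reached by necessity in 100 of 100 drawn splits, with 24 and 30 calls in the highest other, so these counts say nothing about chance. At an unadjusted p under 0.05, 41 of 100 splits gave at least the 155 probes of the interaction, with 687 in the highest other, and 5 of 100 gave at least the 375 probes of the average soil difference, with 513 in the highest other, so chance is not excluded for either of these counts. Whether the splits with many more calls than the real one follow a structure of the samples was not tested.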
